A study of Mus musculus with 12 samples.

How the data were processed

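The samples were 6 H3K27ac ChIP-seq libraries of cultured mouse adipocyte progenitors, 3 Azin2-/- (replicates 1, 2 and 8) and 3 wild-type (replicates 1, 2 and 2b). The 6 input libraries that belong to them have no processed files and were not analysed here. Per the labels' protocols, cells from subcutaneous fat were cultured for 1 week in medium with 4.5 g/l glucose and 10% serum. They then had 2 days with 5 µg/ml insulin, 0.5 mM IBMX, 1 µM dexamethasone and 1 µM rosiglitazone, and 5 days with insulin alone, with fresh medium every 2 days.

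The deposited files are peak lists, 1 per library, on the mouse genome build mm10 (GRCm38), per the submitters' processing notes. The aligner, the peak caller, the handling of duplicates and the control library are not given in the sources used here. Each deposited list gives for every peak its position, a score, a fold ratio of the summit over its local background, a -log10 p-value, a -log10 q-value and the summit position. The deposited score is the whole part of 10 times the -log10 p. The weakest deposited p-value is about 0.1, so the lists were not filtered to strong peaks. Scores, fold ratios and p-values are the authors' and were used only to describe, rank and filter peaks within a list, never to compare a peak between libraries. Fold and p together imply a whole-number pileup and a background level, if the fold was formed with a pseudocount of 1. This was checked: within 0.001 on the log10 scale 100% of peaks gave a whole pileup, against 1.29 to 16.4% when a small random amount was added to each -log10 p. The background level so obtained stands in for depth, since read totals are not given. It is descriptive and entered no test.

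Peaks on chromosomes 1 to 19 and X were used, with equal coordinates counted once. The main lists were the 30000 peaks of smallest p per library, ties broken by fold and position. Overlapping peaks of the 6 lists were merged by 1 bp or more into regions, and a region was held by a library that had at least 1 bp of a main peak there. The reference table gives spans of genes on GRCm38 without strand or exons, so transcription start sites could not be placed. Both ends of each protein-coding gene (21631 genes) with 1 kb on each side took the place of promoters, and summits fell into 3 classes: at a gene end, inside a gene, or between genes.

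Single values per library were compared by two-sided exact permutation tests over the 10 splits of the libraries, whose smallest p is 0.1. For gene loci, the covered length of main peaks within the gene body and 5 kb on each side was scaled to equal total cover per library, 500 bp were added and the log2 was taken, for genes with a mean of at least 500 bp. For regions, 200 bp were added and the minimum mean was 200 bp. Both were tested with limma (eBayes with a mean trend) and Benjamini-Hochberg adjustment at 0.05. The lists of genes, 23 in number, were tested with camera at a preset correlation of 0.01 where at least 5 members were measured, and again with an estimated correlation and with fry. All symbols of the lists were found in the reference table. Camera compares a list with the other genes, whereas fry asks whether its members move on balance to 1 side. For the extracellular matrix list the fry adjusted p was 0.619, and for the Wnt and TGF-beta list in the 5000 strongest peaks it was 0.00419.

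Gene lists, tests, alternatives and the rule for named genes were fixed before the data were examined. The rule named the 10 genes of largest log2 difference in each direction among those past the threshold. Where fewer than 5 passed in a direction, it named the 5 of smallest p in that direction whose libraries do not overlap between genotypes, given as not passing. It always named 25 genes of polyamine metabolism, adipogenesis and progenitors: Azin2, Odc1, Azin1, Oaz1, Srm, Sms, Sat1, Smox, Pparg, Cebpa, Cebpb, Klf15, Fabp4, Adipoq, Plin1, Lpl, Cd36, Fasn, Scd1, Ucp1, Pdgfra, Dlk1, Dpp4, Wnt10b and Cdkn1a. Of these, 18 were tested and 7 fell under the minimum: Sat1, Adipoq and Ucp1 had no cover, Fabp4 had cover in 1 library, Lpl in 2, and Scd1 and Dpp4 in 3 each. For regions the rule named 5 in each direction in the same way, with the gene they overlap, and for each list its 2 members of smallest p in each direction. The genes named at a q of 0.01 or less and further members in the 5000 strongest peaks fall outside it. Not every gene that the rule names is printed.

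Alternatives fixed at the same time were other list lengths (15000 and 60000), q thresholds, all deposited peaks, other pseudocounts, minimums, windows and scalings, fixed windows of 250 bp on each side of the summits, the replicate number as a block, wild-type replicates 2 and 2b averaged, and each library left out in turn. Lists of the 5000 and 10000 strongest peaks, ends of 2 kb and a term for the 2 longest lists were added after the data were examined. The windows of 2 kb around transcription start sites were not run for lack of strand.

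The tests were tried on simulated data. At the spread measured here, the gene locus test (11670 genes) recovered 0% of genes changed by 1 and 42% of those changed by 3 on the log2 scale, with 0 false calls. The region test (22206 regions) recovered 0% and 6%. At 0.25 times that spread the gene locus test recovered 85% and 100% and made 7 false calls. A list of 30 genes shifted by -0.7 was recovered by camera. The simulated genes varied independently and no unshifted list was tried, so this does not check the preset correlation. Software was Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9, and R 4.3.3 with limma 3.58.1.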

Results

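Azin2 encodes antizyme inhibitor 2, a protein that binds antizyme and thereby releases ornithine decarboxylase, the enzyme that opens polyamine synthesis. H3K27ac, the acetylation of lysine 27 on histone H3, marks active promoters and enhancers, and was profiled here by ChIP-seq in Azin2-/- and wild-type mouse cells. The cells were progenitors from subcutaneous fat, grown for 1 week and then carried through an adipogenic schedule of 2 days with insulin, IBMX, dexamethasone and rosiglitazone followed by 5 days with insulin. The question was where acetylated chromatin differs between the genotypes. Each genotype gave 3 libraries, numbered 1, 2 and 8 for Azin2-/- and 1, 2 and 2b for wild-type. The labels do not say whether the libraries of a genotype came from separate animals, so no p-value here reaches beyond these libraries. Those of the permutation tests, limma and fry measure the spread between the libraries, and those of camera set a list against the other genes.

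Each deposited list held between 742335 and 1217494 peaks. Most peaks were shallow: the share with a pileup of 3 fragments or fewer at the summit was 51.6% in Azin2-/- replicate 8 and between 92.6% and 98.9% in the other libraries. The background depth implied by the deposited fold and p ran from 0.125 fragments per bp in wild-type replicate 1 to 0.957 in Azin2-/- replicate 8, with means of 0.552 ± 0.363 in Azin2-/- and 0.261 ± 0.143 in wild-type (SD, n = 3; two-sided exact permutation p = 0.2). Azin2-/- replicates 1 and 2 had 0.255 and 0.445, and wild-type replicates 2 and 2b 0.41 and 0.249. Comparisons therefore used the 30000 strongest peaks of each library, ranked within each list by the authors' p. These covered 24.2 ± 4.13 Mb in Azin2-/- and 22.3 ± 5.57 Mb in wild-type (SD, n = 3). At a deposited q of 0.05 or less Azin2-/- replicate 1 held 54847 peaks and the other libraries 13843 to 21544. In every library but that one the 30000 strongest thus include peaks that do not reach this q.

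The Azin2 gene itself, on chromosome 4 from 128930233 to 128962456 in GRCm38, carried its strongest peak at the gene end with the higher coordinate in all 6 libraries. In Azin2-/- replicate 1 this peak spanned 128961743 to 128962918, and in wild-type replicate 2b it spanned 128961433 to 128963858. Within the gene and 5 kb on each side, the 30000 strongest peaks covered 1179 ± 311 bp in Azin2-/- and 1670 ± 670 bp in wild-type (SD, n = 3; two-sided exact permutation p = 0.5). Wild-type replicate 2b had 2426 bp, and wild-type replicates 1 and 2 had 1434 and 1150 bp. Azin2-/- replicates 1, 2 and 8 had 1176, 870 and 1492 bp. Over all deposited peaks the order turned, with 9641 ± 2378 bp in Azin2-/- and 7882 ± 4653 bp in wild-type (SD, n = 3; exact permutation p = 0.8). A peak list does not measure the transcript, and the nature of the knockout allele is not given in the sources used here, so the locus tests neither genotype label.

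**Figure D1:**
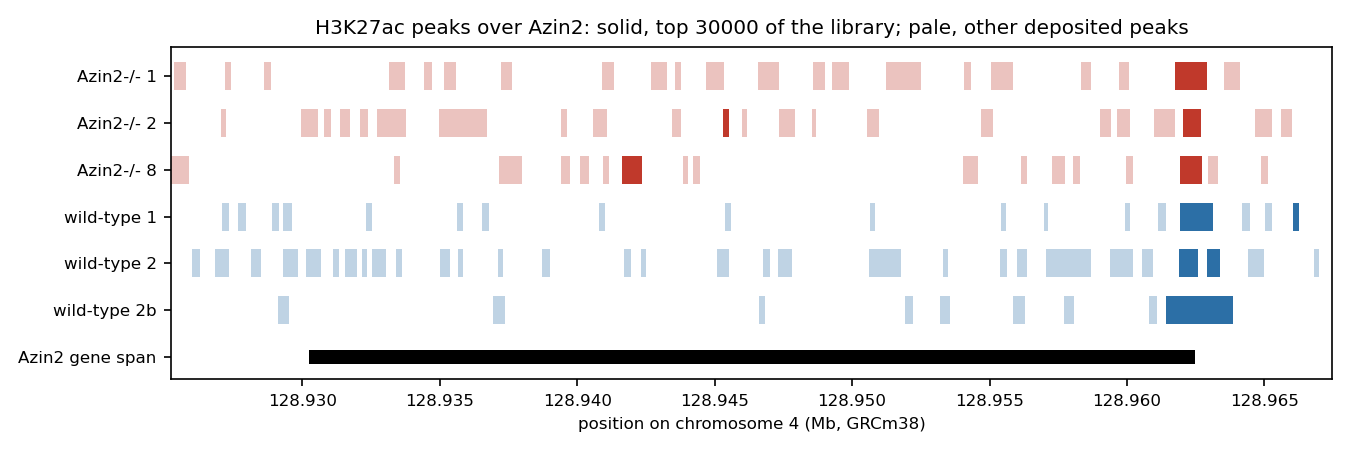
Peaks over the Azin2 gene and its flanks by library, with position on chromosome 4 on the horizontal axis, Azin2-/- libraries in red and wild-type libraries in blue. Solid boxes are peaks among the 30000 strongest of a library and pale boxes are its other deposited peaks. Every library has a solid box at the gene end near 128962456. That of Azin2-/- replicate 2 had a -log10 q of 1.2 and so did not reach a q of 0.01.

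A total of 3889 of 21631 protein-coding genes had a peak within 1 kb of a gene end in every library. Whether any gene list was enriched among them was not tested. Among them were 11 of 50 genes of lipid storage, including Plin1, which coats lipid droplets, Fasn, the fatty acid synthase, and Dgat2, which makes triglyceride. They also included 9 of 26 adipogenic transcription factors, among them Cebpa, Cebpb and Ebf1 but not Pparg, and 10 of 25 polyamine genes, among them Odc1, Azin1, Oaz1, Srm and Azin2. The Wnt and TGF-beta list had 20 of 40 such genes, including Tcf7l2, Smad3 and Tgfbr1, and the list of acetyl-CoA supply and histone acetylation had 13 of 38, including the acetyltransferases Ep300 and Crebbp. By contrast, Adipoq, Ucp1 and Sat1 had no peak of this strength within the gene and 5 kb on each side in any library, and Fabp4 had one in wild-type replicate 2b alone.

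Genes with a peak at a gene end numbered 9041 ± 1742 in Azin2-/- libraries and 7648 ± 1150 in wild-type libraries (SD, n = 3; two-sided exact permutation p = 0.4). The share of summits within 1 kb of a gene end was 26.2% ± 4.98 in Azin2-/- and 21.8% ± 2.84 in wild-type (SD, n = 3; exact permutation p = 0.3, adjusted 0.45 over the 3 classes). Summits farther inside genes made up 35.7% ± 0.752 and 36.4% ± 3.05 (SD, n = 3; exact permutation p = 0.8, adjusted 0.8), and summits between genes 38.1% ± 4.56 and 41.8% ± 1.24 (SD, n = 3; exact permutation p = 0.2, adjusted 0.45). At a deposited q of 0.01 or less, Azin2-/- lists held 17012 ± 8342 peaks over 16.4 ± 9.41 Mb and wild-type lists 10775 ± 3395 peaks over 10.9 ± 4.56 Mb (SD, n = 3; exact permutation p = 0.4 for number and 0.5 for length). Azin2-/- replicate 1 alone held 26146 such peaks, and without it the difference in mean number went from 6236 to 1669 and that in length from 5.52 to 0.289 Mb. Without it the difference in the number of genes with a peak at a gene end also went from 1393 to 393, and that in the share of summits there from 4.41 to 1.55 points. The difference in the share of summits between genes went from -3.67 to -1.1 points without that library. With 3 libraries against 3 an exact permutation p cannot go below 0.1, so none of these comparisons could pass a threshold of 0.05.

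**Figure D2:**
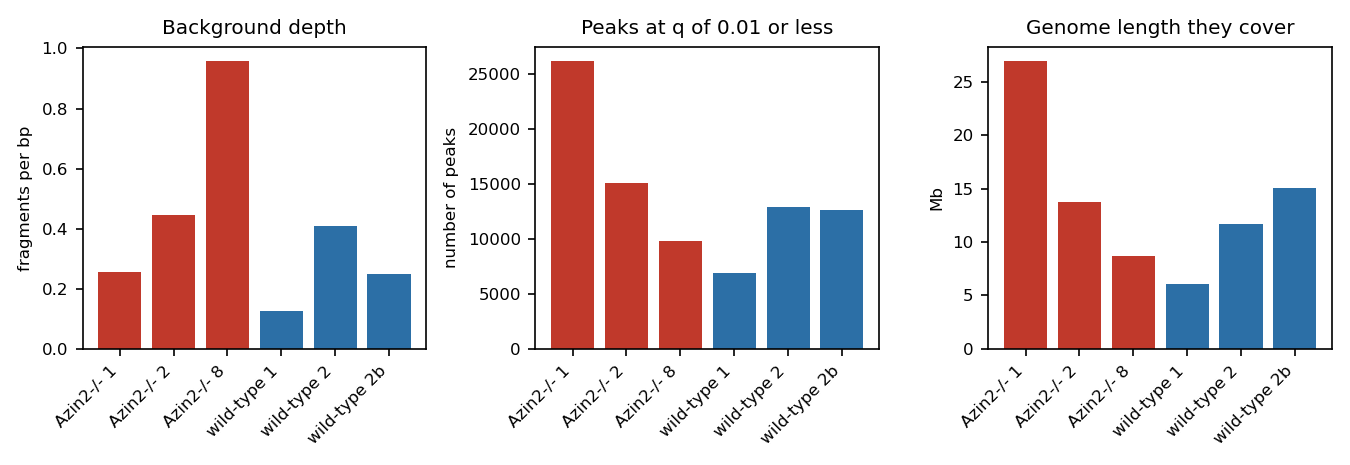
Depth and list measures of the 6 libraries, each bar a library, Azin2-/- in red and wild-type in blue: background depth in fragments per bp, number of peaks at a q of 0.01 or less, and the length they cover in Mb. Azin2-/- replicate 1 stands highest in such peaks, with 26146, and wild-type replicate 1 lowest, with 6858.

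In the 30000 strongest peaks the libraries of a genotype overlapped each other little more than they overlapped the other genotype. The mean Jaccard index, the shared length over the joint length of a pair of lists, was 0.173 within and 0.163 between genotypes, a difference of 0.00996 (exact permutation over the 10 splits of the 6 libraries, p = 0.2). Without Azin2-/- replicate 2 the difference was -0.00753 and without Azin2-/- replicate 8 it was -0.00462, and among all deposited peaks it was -0.0022. It was 0.00035 without Azin2-/- replicate 1, 0.013 without wild-type replicate 1, 0.0284 without wild-type replicate 2 and 0.0302 without wild-type replicate 2b. In the 5000 strongest peaks, a length chosen after the data were examined, it was 0.0329, with 0.314 within and 0.281 between genotypes, and 0.0215 in the highest other split (exact permutation p = 0.1).

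Peaks found at gene ends in every library of 1 genotype and in none of the other were mostly in Azin2-/- lists. There were 184 such genes in Azin2-/- and 13 in wild-type. The counts were 117 and 164 in the 5000 strongest peaks, a length chosen after the data were examined. From the gene lists, the Azin2-/- set held Hdac3, a histone deacetylase, Cpt2, which carries fatty acids into mitochondrial oxidation, Dohh, which completes hypusine on the translation factor eIF5A from a polyamine, and the creatine kinases Ckm and Ckb. It also held Bmp8b, a growth factor of brown fat, Creb5 and Myod1, while the wild-type set held Thbs1, the matrix protein thrombospondin 1. These counts are not a test of any single gene. For Azin2-/- and wild-type they were 206 and 141 without Azin2-/- replicate 1, 453 and 17 without Azin2-/- replicate 2, 416 and 14 without Azin2-/- replicate 8, 233 and 53 without wild-type replicate 1, 399 and 80 without wild-type replicate 2, and 607 and 66 without wild-type replicate 2b.

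Merged regions showed the same imbalance. Of 128480 regions, 4149 were held by all 6 libraries and 110221 by 1 library, while 530 were held by all Azin2-/- and no wild-type libraries and 33 by all wild-type and no Azin2-/- libraries. Of the 530 regions 2 had no deposited peak of any strength in any wild-type library and 298 had one in all 3. Of the 33 regions 3 had none in any Azin2-/- library and 9 had one in all 3. The share that chance would give was not computed. Among the 5000 strongest peaks, a length chosen after the data were examined, the counts were 160 and 176. The counts for Azin2-/- and wild-type were 768 and 167 without Azin2-/- replicate 1, 1418 and 35 without Azin2-/- replicate 2, 1887 and 37 without Azin2-/- replicate 8, 607 and 328 without wild-type replicate 1, 992 and 434 without wild-type replicate 2, and 1071 and 363 without wild-type replicate 2b.

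**Figure D3:**
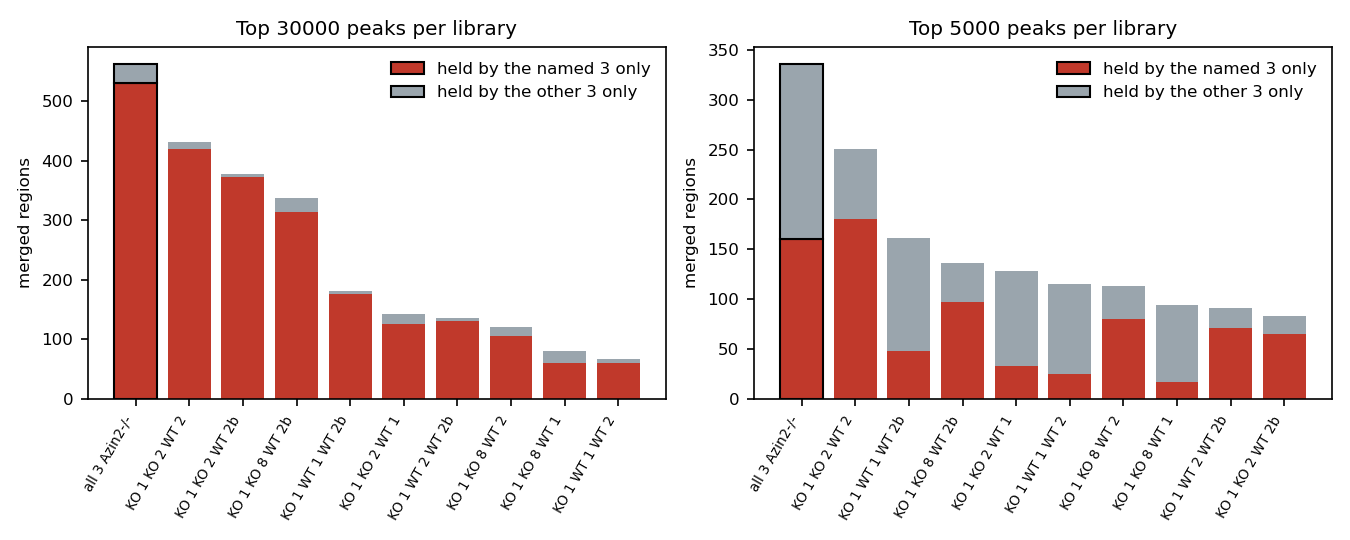
Number of merged regions held by all 3 libraries named under a bar and none of the others (red) or the reverse (grey), for the 10 splits of the libraries (KO, Azin2-/-; WT, wild-type), with the genotypes outlined, in the 30000 strongest peaks on the left and the 5000 strongest on the right. For the genotypes the counts are 530 and 33 on the left and 160 and 176 on the right.

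Tested 1 region at a time by covered length, the named regions with more cover in Azin2-/- lay in Zfp536, Ano8 and Igf2 and at Apba3 with Tjp3 and at Mfsd12. Each of these had no cover in any wild-type library. The region in Igf2, which encodes insulin-like growth factor 2, on chromosome 7 from 142657988 to 142659964, had 1656 ± 125 bp in Azin2-/-, and the region in Zfp536, chromosome 7 from 37768583 to 37771412, had 2117 ± 449 bp (SD, n = 3). The named regions with less cover in Azin2-/- overlapped ends of the transcription factor genes Zfp710, Tcf7l2 and Foxp1, the coregulator gene Zmiz1 and the focal adhesion gene Zyx. At Zfp710, chromosome 7 from 80024554 to 80028182, cover was 1537 ± 105 bp in Azin2-/- and 3595 ± 681 bp in wild-type (SD, n = 3), a log2 difference of -1.11 with SE 0.16 and a limma adjusted p of 0.181. At Tcf7l2, the main nuclear partner of beta-catenin in Wnt signalling, chromosome 19 from 55740833 to 55745238, it was 1678 ± 473 and 3421 ± 636 bp, a log2 difference of -0.97 (SD, n = 3; limma adjusted p = 0.603). At Foxp1, chromosome 6 from 99519187 to 99523642, the log2 difference was -1.04, at Zyx -1.23 and at Zmiz1 -0.43 (limma adjusted p = 0.603 for each). With fixed windows of 250 bp on each side of the summit, each named region was matched to the fixed-window region that overlaps it most. The value was then 1.81 at Foxp1, the same as at Zfp536 and at Apba3 with Tjp3, and -0.00 at the other 4. Such windows register only which libraries have a summit there. These values therefore show neither a reversal over the Foxp1 region nor equal cover at the other 4.

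None of these regions passed the test in the 30000 strongest peaks. In limma 0 of 22206 regions had an adjusted p under 0.05, and 899 had a higher and 324 a lower value in Azin2-/- at an unadjusted p under 0.05. With fixed windows of 250 bp on each side of the summit 529 regions were higher and 39 lower, with the 60000 strongest peaks 13 and 37, with no minimum length 16 and 46, and at a q of 0.01 or less 0 and 3. All of the 529 had no cover in any wild-type library and all of the 39 none in any Azin2-/- library with these windows. These calls thus restate presence in 1 genotype and are not a separate test. With the 60000 strongest peaks, with no minimum length and at a q of 0.01 or less, limma gave the common trend of spread infinite weight. Each region's own spread between libraries then had no part in the calls. Of the 10 named regions 7 had a limma adjusted p under 0.05 in at least 1 alternative. That at Foxp1 did in 4, those at Zfp536, Zfp710, Zmiz1 and Tcf7l2 in 2 each, and those at Zyx and at Apba3 with Tjp3 in 1 each. The passes with fixed windows, at Foxp1, Zfp536 and Apba3 with Tjp3, restate presence in 1 genotype. That at Foxp1 was for a stretch covered in Azin2-/- alone and so had the other sign than the whole region.

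**Figure D4:**
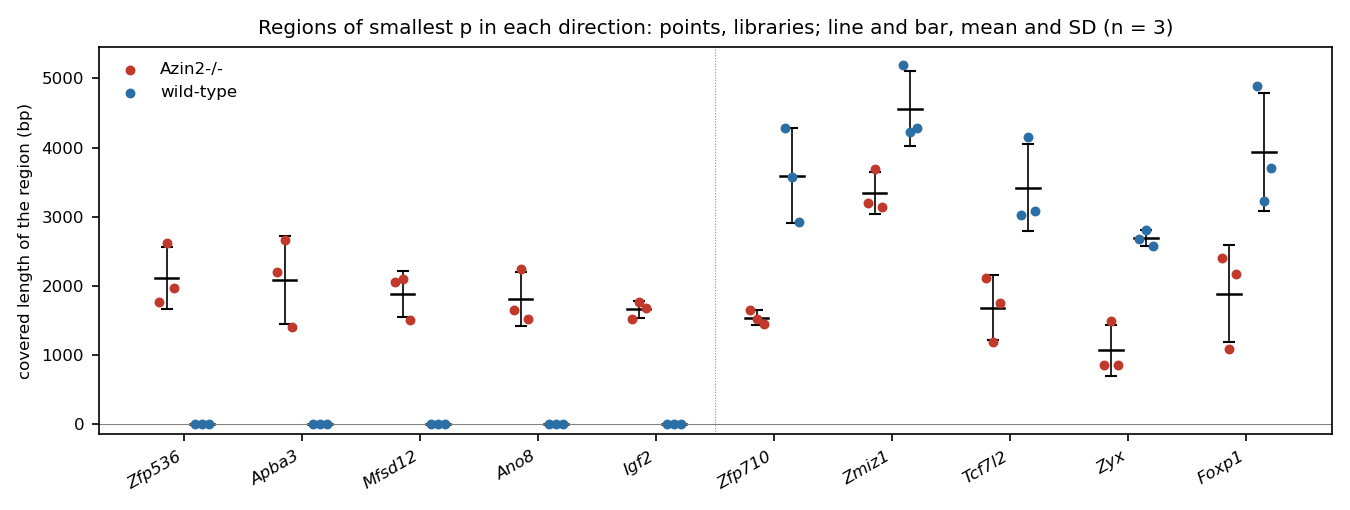
Covered length in bp of the 10 named regions in each library, each point a library, Azin2-/- in red and wild-type in blue, with a line at the mean and a bar for the SD (n = 3). The 5 regions with more cover in Azin2-/- have 0 bp from the 30000 strongest peaks of every wild-type library. None of the 10 passed the region test in these peaks.

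Over whole gene loci, the gene body and 5 kb on each side, the named genes with more cover in Azin2-/- included Kcnh2, a cardiac potassium channel, Bmp8b, Mfsd12 and Cfap61, a ciliary protein. Kcnh2 had 6482 ± 383 bp in Azin2-/- and 1931 ± 311 bp in wild-type, and Mfsd12 had 3286 ± 493 and 730 ± 87.3 bp (SD, n = 3). Bmp8b had 2649 ± 1526 bp in Azin2-/- and was listed at 0 in wild-type (SD, n = 3). The named genes with less cover were Mlip, Slc14a2, Gnaq, the G protein alpha subunit q, Ctsh and Tacc2. Gnaq had 1516 ± 1022 bp in Azin2-/- and 6434 ± 2506 bp in wild-type, and Mlip had 202 ± 196 and 2515 ± 734 bp (SD, n = 3). The limma adjusted p was 0.743 for each of these genes.

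Among the adipogenic regulators named beforehand, Cebpb, an early factor of adipogenesis, had 1268 ± 266 bp in Azin2-/- and 3463 ± 1215 bp in wild-type, with no overlap between genotypes (SD, n = 3; log2 difference -1.12, limma adjusted p = 0.743). Pparg, the master regulator of fat cells, went the other way with 1392 ± 200 and 655 ± 695 bp (SD, n = 3; log2 difference 0.91, limma adjusted p = 0.792), Cebpa differed by -0.17 and Klf15 by -0.50 on the log2 scale. The progenitor gene Dlk1 had 1624 ± 783 bp in Azin2-/- and 368 ± 638 bp in wild-type (SD, n = 3; limma adjusted p = 0.758), while Pdgfra differed by -0.56 and Wnt10b by -0.82. In the polyamine pathway no gene passed, and the log2 differences were -0.44 for Azin2, -0.00 for Odc1, 0.37 for Azin1, -0.41 for Oaz1, -0.17 for Srm, 0.41 for Sms and 0.05 for Smox. The adipocyte genes Plin1, Cd36 and Fasn differed by 0.29, 0.10 and -0.30, and the cell cycle inhibitor Cdkn1a by -0.56. None of these 18 genes passed the test, and 12 of them had the other sign in at least 1 alternative, Odc1 in 9, Smox in 7, Oaz1 in 6 and Plin1 in 5.

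In limma 0 of 11670 gene loci had an adjusted p under 0.05, with 506 higher and 249 lower in Azin2-/- at an unadjusted p under 0.05. The values of the genotypes did not overlap at 1359 loci, or 11.6%, where chance gives 10% and the highest other split of the 6 libraries had 1598. At a q of 0.01 or less 22 genes were higher and 4 lower, and with fixed windows 43 and 16. For the calls at that q limma weighted the common trend of spread with 98.65 degrees of freedom against 4 of each gene's own. In the main test that weight was 6.817. With fixed windows that weight was 0.7527, so each gene's own spread between libraries counted most. Cover there comes largely in steps of 1 window, so nearly tied values in a genotype can give small p-values. How many of the 43 and 16 calls arose in this way was not tested. The lists at that q also differed in length, from 6858 to 26146 peaks. At that q the 4 lower genes were Foxp1, Tcf4, Gnaq and Hoxc9, and 18 of the 22 higher genes, 15 of them protocadherin gamma genes, overlap each other at 1 locus on chromosome 18 and so share their peaks. The other 4 were Hcn2, Igf2bp1, Syt7 and Bsn. These genes were chosen after their values were seen.

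Of the gene lists fixed beforehand, the extracellular matrix list was lower in Azin2-/-. Its 24 measured genes were lower than other genes by camera, with a median log2 difference of -0.40 and 6 of 24 positive (camera adjusted p = 0.00278, but adjusted p = 0.554 with an estimated correlation and 0.619 by fry). The mean log2 difference minus that of all genes was -0.58 over all libraries, -0.21 between Azin2-/- replicate 1 and wild-type replicate 2b and -0.26 between replicate 2 of each genotype, the pairs of near equal background depth. The means themselves were -0.47, -0.02 and -0.21. Col1a1, the main fibrillar collagen gene, had 180 ± 312 bp in Azin2-/- and 1903 ± 1358 bp in wild-type, and Loxl1, which crosslinks elastin, had 1444 ± 420 and 3595 ± 1864 bp (SD, n = 3). Timp3, an inhibitor of matrix proteases, and Col6a2 were positive, with log2 differences of 0.49 and 0.37. No member passed limma alone: 0 did over all genes and 0 adjusted over the list alone, and 2 had an unadjusted p under 0.05. Without wild-type replicate 1 the median was -0.16 and the camera adjusted p 0.406, and in the 5000 strongest peaks they were -0.72 and 0.166. A split of the 6 libraries that mixes genotypes gave this list an unadjusted camera p of 0.000182, against 0.000139 for the genotypes. A camera p this small at the preset correlation thus also arose without the genotype contrast.

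The Wnt and TGF-beta list, which includes signals that restrain adipogenesis, had 11 of 35 genes positive and a median of -0.32, just outside the threshold (camera adjusted p = 0.059, and adjusted p = 0.554 with an estimated correlation). Its mean was -0.21, and -0.36 without Azin2-/- replicate 1 to -0.07 without Azin2-/- replicate 8. It was 0.087 between Azin2-/- replicate 1 and wild-type replicate 2b and -0.315 between replicate 2 of each genotype. Fst, which encodes the activin antagonist follistatin, had 1496 ± 765 bp in Azin2-/- and 4168 ± 2025 bp in wild-type, and Lef1 had 4488 ± 192 and 2200 ± 1387 bp (SD, n = 3). The thermogenic list had 16 of 20 genes positive with a median of 0.24 (camera adjusted p = 0.402). With 2 kb on each side of the gene ends, windows chosen after the data were examined, it passed (camera adjusted p = 0.0126, but adjusted p = 0.53 with an estimated correlation). Its Bmp8b and Ckb, the creatine kinase of brown fat, passed when adjusted over the list alone, with adjusted p of 0.0097 and 0.0388, and 0 of its genes passed over all genes in limma, where 2 had an unadjusted p under 0.05. Ckb had 1534 ± 246 bp in Azin2-/- and was listed at 0 in wild-type (SD, n = 3).

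The lipid storage list had a median of -0.13 with 13 of 30 genes positive (camera adjusted p = 0.171). Its members differed in sign: Lipe, the hormone-sensitive lipase, had 1652 ± 355 bp in Azin2-/- and 92.6 ± 160 bp in wild-type, whereas Mgll, the monoglyceride lipase, had 971 ± 493 and 2327 ± 1059 bp (SD, n = 3). The adipogenic transcription factors had a median of -0.01 (adjusted p = 0.738), with Klf5 and Egr2 leading the positive genes and Cebpb and Ebf1 the negative ones. The progenitor and fibroblast list had a median of -0.28 (adjusted p = 0.364), with Icam1 and Dlk1 positive and Prrx1 and Dcn negative. Polyamine metabolism had a median of -0.04 with 9 of 20 genes positive (adjusted p = 0.812), led by Dohh at 1481 ± 739 and 142 ± 245 bp (SD, n = 3). The list of acetyl-CoA supply and histone acetylation had a median of 0.00 (adjusted p = 0.642), with Hdac3 at 2475 ± 394 and 870 ± 199 bp (SD, n = 3) and the acetyltransferase gene Kat6b at a log2 difference of -0.93.

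Medians of the other metabolic and growth lists were -0.12 for fatty acid oxidation and mitochondria (adjusted p = 0.648), -0.07 for glycolysis (0.868), 0.08 for cell cycle (0.783), -0.24 for senescence and p53 (0.211), -0.04 for inflammation and interferon (0.364) and -0.15 for housekeeping genes (0.409). No list of markers of other cell types passed the test, and their directions differed. All 7 endothelial, 6 macrophage, 5 mesothelial and 5 Schwann and neural markers that were measured had positive differences, with medians of 0.64, 0.49, 0.50 and 0.86 (adjusted p = 0.211, 0.402, 0.364 and 0.171), except that 5 of 6 macrophage markers were positive with quantile normalization. With flanks of 20 kb the endothelial markers passed (camera adjusted p = 0.0211, but adjusted p = 0.645 with an estimated correlation). Epithelial markers had a median of 0.08 (0.961, with camera's direction down), and pericyte and smooth muscle markers -0.23 (0.897). Means had the other sign than the medians for adipogenic transcription factors, fatty acid oxidation, glycolysis, polyamine metabolism, acetyl-CoA supply and pericyte markers, and the median turned without scaling or with quantile normalization for all of these but fatty acid oxidation and pericyte markers, and for the inflammation and cell cycle lists. Skeletal muscle and lymphocyte markers had fewer than 5 measured genes, and the sex-linked list had no measured gene.

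**Figure D5:**
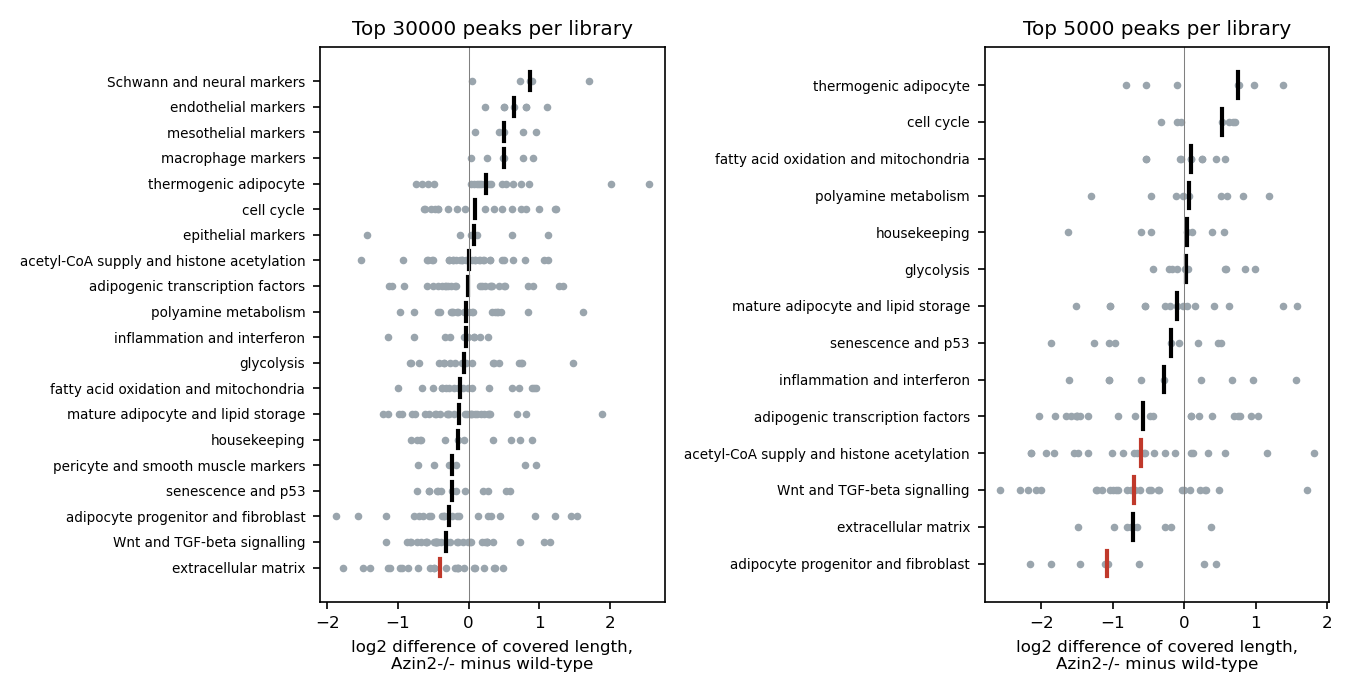
Log2 difference in covered length, Azin2-/- minus wild-type, of the members of each gene list (grey points) with the list's median (bar, red where the camera adjusted p is under 0.05), in the 30000 strongest peaks on the left and the 5000 strongest on the right. The extracellular matrix list, median -0.40, is red on the left; the Wnt and TGF-beta list, median -0.70, is among the 3 in red on the right.

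Among the 5000 strongest peaks of each library, a length chosen after the data were examined, 3 lists passed camera at its preset correlation and none with an estimated one. The estimated correlation was -0.02 for the Wnt and TGF-beta list, -0.01 for the acetylation list and 0.077 for the progenitor list. For the Wnt and TGF-beta and the acetylation lists it thus lay below the preset 0.01. The unadjusted fry p of these lists was, in the same order, 0.000299, 0.0019 and 0.0187. The Wnt and TGF-beta list had less covered length than other genes, with 6 of 29 genes positive and a median log2 difference of -0.70 (camera adjusted p = 0.00171, but adjusted p = 0.171 with an estimated correlation). Wnt5b, Wnt5a, the receptor gene Bmpr1a and the coreceptor gene Lrp6 had no peak of this rank in any Azin2-/- library, and 2540 ± 791, 1993 ± 470, 1805 ± 514 and 1608 ± 236 bp in wild-type (SD, n = 3). Together with Fst, at 387 ± 671 and 2634 ± 1173 bp (SD, n = 3), 5 of its genes passed adjusted over the list alone and 0 over all genes in limma. The list of acetyl-CoA supply and histone acetylation also had less covered length, with a median of -0.61 and 6 of 22 genes positive (camera adjusted p = 0.0335, but adjusted p = 0.253 with an estimated correlation). Adjusted over the list alone, 5 of its genes passed and 0 over all genes in limma. Among the 5, the acetyltransferases Kat2b and Kat6b and the pyruvate dehydrogenase subunit Pdha1 were lower and the deacetylase Hdac1 was higher. Kat2b had 0 bp in Azin2-/- and 1771 ± 607 bp in wild-type, and Hdac1 had 1273 ± 335 bp in Azin2-/- and 0 bp in wild-type (SD, n = 3).

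The progenitor and fibroblast list had 2 of 8 genes positive there and a median of -1.09 (camera adjusted p = 0.0391, but adjusted p = 0.325 with an estimated correlation). Fbn1, which encodes fibrillin, and the transcription factor gene Sox9 passed adjusted over the list alone, listed at 0 in Azin2-/- with 1755 ± 438 and 1362 ± 433 bp in wild-type (SD, n = 3), and 0 of the list passed over all genes in limma. The unadjusted camera p of this list was 0.0533 without Azin2-/- replicate 1, 0.223 without Azin2-/- replicate 8 and 0.0835 without wild-type replicate 2b, against 0.00839 with all libraries. The adipogenic transcription factors had a median of -0.58 (adjusted p = 0.125), with Ebf3, Nfib and Cebpb among the negative genes. Bbc3, a p53 target that promotes cell death, had the smallest p of all genes at this length, 966 ± 135 bp in Azin2-/- and 4844 ± 875 bp in wild-type (SD, n = 3; log2 difference -1.86, limma adjusted p = 0.152).

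Of these genes Bmpr1a, Fst, Lrp6, Kat2b, Kat6b, Pdha1, Fbn1, Sox9, Nfib and Bbc3 had a gene-end peak among the 30000 strongest of all 6 libraries. In limma 0 of 5862 gene loci passed at this length, with 248 higher and 341 lower at an unadjusted p under 0.05. With fixed windows at the summits the mean log2 difference was -0.17 for the Wnt and TGF-beta list, -0.14 for the progenitor list and 0.15 for the acetylation list, against -0.72, -0.95 and -0.62 with the deposited peak extents. The minimum mean of 500 bp removes genes with 1 such window in 1 genotype alone, so the members compared may differ. The unadjusted camera p with these windows was 0.704, 0.815 and 0.169, and over 24 alternatives the lists passed in 7, 1 and 1, with adjusted p from 0.00171 to 0.532, from 0.0391 to 0.819 and from 0.0335 to 0.932.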

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

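The use of the 5000 strongest peaks with every test in them, the test of weak peaks and the splits for the regions, and the comparison with other left-out libraries were chosen only after the results were seen.

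In Azin2-/- replicate 1, 7 peaks on the Y chromosome had a q of 0.01 or less, above the limit of 3 that a count of 0 allows. The Y chromosome was outside the comparisons. The other libraries had 2, 0, 2, 3 and 1 such peaks, and all 6 had weaker peaks in the Y-linked gene Uty, between 27 and 81 of them. Azin2-/- replicate 1 also held the most peaks at this q over all sequences, 26153 against 6860 to 15093 in the others. The limit of 3 takes no account of list length, so the count of 7 does not by itself mark that library as unusual. No explanation was tested.

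Regions held by 1 genotype alone were 530 in Azin2-/- and 33 in wild-type lists, a ratio of 16.1 that was 0.909, 4.11, 12.7 and 3.8 in the 5000, 10000, 15000 and 60000 strongest peaks, 71.4 at a q of 0.01 or less and 9.45 with at least 50% of the merged region covered. It went both ways with list length, so weak peaks near the end of the lists stay open as its source. Without Azin2-/- replicate 1, the library with most enriched peaks, it was 4.6, between the bounds set beforehand, against 40.5 and 51 without Azin2-/- replicates 2 and 8, which leaves that library open. Without the shallow wild-type replicate 1 it was 1.85, under the bound of 2 set beforehand, and 2.29 and 2.95 without wild-type replicates 2 and 2b. Leaving out a library raises both counts by construction, and the ratio fell without each wild-type library in turn. This test therefore decides nothing, and a difference between genotypes stays open. The 10 splits are too few for a share under 0.05, with 563 regions for the genotypes and 432 in the highest other split.

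The Wnt and TGF-beta list was lower in Azin2-/- among the 5000 strongest peaks, but not past the threshold with an estimated correlation (adjusted p = 0.171). In the pairs of libraries with near equal background depth the mean log2 differences were -0.80 and -0.697, so there the lower cover came without a difference in that depth. The length was chosen after these same libraries were seen. In the 30000 strongest peaks the same pairs gave 0.087 and -0.315, so depth is not excluded. The lower cover among the 5000 strongest does not rest on 1 library, as the mean nearest to 0 with a library left out was -0.701. Peak width stays open. With fixed windows at the summits the mean was -0.17 and the camera p 0.704. This may reflect narrower peaks in Azin2-/- or only that such windows cannot register width. The minimum mean of 500 bp also removes genes with 1 such window in 1 genotype alone, so the members compared may differ. The fixed windows thus cannot decide on width. The 10 splits are too few for a share under 0.05, with a camera p of 0.000122 for the genotypes and 0.0262 for the other split nearest to it, and a difference between genotypes stays open, as untested.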

How the results depend on the processing

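The lists of the 5000 and 10000 strongest peaks, the 2 kb gene ends and every test within the 5000 strongest peaks were chosen only after the results were seen. The cause was not tested for any change below, unless stated.

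Of the main results under their alternatives, 201 values counted as unchanged and 51 counts moved by over 1.5 times. A further 5 turned direction and 3 no longer passed. Unchanged meant the same direction and side of the threshold for tested values, and a move of at most 1.5 times for counts. The unchanged counts include numbers of calls that stayed at 0. Exact permutation p-values cannot go below 0.1 here, so the side of the threshold was fixed for the values they tested. How many of the 201 could have changed was not examined. The within-minus-between Jaccard difference was -0.0022 among all deposited peaks and -0.00753 to 0.0302 with 1 library left out. The share of summits inside genes differed by -2.49 to 0.347 points with 1 library left out, and the Azin2 locus by 1759 bp over all deposited peaks. Of 95 named genes 30 had the other sign in some alternative, and of 10 named regions 1 did, while 2 genes, Bmp8b and Gnaq, and 7 regions passed in some alternative. That 1 region, at Foxp1, had the other sign only with fixed windows, which stand for a stretch of it and not the whole. The median log2 difference over all regions, 0.17, was 0.29 without scaling, -0.22 with no minimum length, 0.65 with wild-type 2 and 2b averaged and -0.01 to 0.46 with 1 library left out.

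Regions in Azin2-/- alone were 160 in the top 5000, 226 in the top 10000 and 607 to 1887 with 1 library left out. Regions in wild-type alone were 176, 55, 130 in the top 60000, 5 at a q of 0.01 or less and 35 to 434 with 1 library left out. Leaving out a library raises such counts by construction, since fewer libraries must hold or lack the region. Genes with a gene-end peak in Azin2-/- alone were 117, 119 and 122 in the top 5000, 10000 and 60000, and 206 to 607 with 1 library left out. Those in wild-type alone were 164, 46 and 38 in the same lists, 23 in the top 15000, 4 at a q of 0.01 or less and 14 to 141 with 1 library left out.

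The gene locus test called 22 higher and 4 lower at a q of 0.01 or less and 43 and 16 with fixed windows. Each other alternative, left-out libraries included, called 0 (limma, 11670 genes, 755 at an unadjusted p under 0.05). The region test called 13 and 37 in the top 60000, 0 and 3 at a q of 0.01 or less, 529 and 39 with fixed windows and 16 and 46 with no minimum.

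Camera called 2 lists in the top 15000, at a q of 0.01 or less, in the top 10000, with a pseudocount of 100 bp and with 2 kb gene ends, 3 in the top 5000 and with 20 kb flanks, 0 with an estimated correlation and 0 to 2 with 1 library left out. These included the thermogenic list with 2 kb gene ends (adjusted p = 0.0126) and the endothelial markers with 20 kb flanks (0.0211). The extracellular matrix list passed in 22 of 24 alternatives, with adjusted p from 0.000136 to 0.406. Its median was -0.72 in the top 5000 (adjusted p = 0.166, 9 genes measured), -0.69 to -0.16 with 1 library left out and -0.40 with an estimated correlation (0.554). The Wnt and TGF-beta list passed in 7 of 24. In the top 5000 with fixed windows the acetylation list turned to 0.15.

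With the replicate number as a block, limma called 0 genes and 0 regions, with 710 higher and 198 lower genes at an unadjusted p under 0.05 (587 and 250 with 2b given the number 2), and the extracellular matrix median was -0.45 or -0.51. Only numbers 1 and 2 are shared between genotypes, and after removal of genotype means the correlations across genes of these pairs were -0.04 and 0.12, the latter the highest of the 9 pairs across genotypes. A batch shared by the libraries of number 2 is thus not excluded. Windows around transcription start sites were not run. Depth was low: in every library but Azin2-/- replicate 8 at least 92.6% of the deposited peaks held 3 fragments or fewer, and the median among the 30000 strongest was 3 to 8. How far this limits the results was not tested.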

Other observations

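The tests of the neuronal gene family, the reading of its camera p beside the splits, the splits of the gene locus test, the region test and the gene ends, and all measures of the 5000 strongest peaks were chosen only after the results were seen.

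Among the 5000 strongest peaks, 829 genes had a gene-end peak in all 6 libraries, including the Wnt pathway gene Tcf7l2, the TGF-beta mediator Smad3, the adipogenic factor Cebpa and the lipid genes Acsl1, Dgat2, Gpd1 and Irs2. In Azin2-/- libraries alone there were 117 such genes, among them Ccnb2, a cyclin of mitosis, and Spi1, a transcription factor of myeloid cells. In wild-type libraries alone there were 164, among them Bmpr1a, Wnt5a, Sox9 and Nfib.

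Genes of neuronal channels and receptors, a family noticed among the leading genes, had 106 of 172 members positive in Azin2-/-, with a mean log2 difference of 0.24. Camera gave p = 0.0491, and p = 0.545 with an estimated correlation of 0.135 in place of the preset 0.01. Of the 10 splits 6, that of the genotypes included, gave a camera p as small, the smallest 2.22e-07. What gave these small values was not tested. A shift of cover to genes of tissues other than fat thus cannot be told from this camera p. In the pairs of libraries with near equal background depth the mean beyond that of all genes averaged 0.117, with 0.308 in one pair and -0.07 in the other, which leaves depth open. That mean, 0.139 over all libraries, was 0.0318 without wild-type replicate 1, 0.0866 without Azin2-/- replicate 2 and 0.0875 without wild-type replicate 2b, each under the bound of 0.1 set beforehand for 1 library as the cause, so no single library can be named.

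The 10 splits of the libraries are too few for a share under 0.05 in any of the following. At an unadjusted p under 0.05 the gene locus test gave 755 genes (highest other split 978), and the region test gave 1223 regions (highest other 1159). For the extracellular matrix list the camera p was 0.000139 (smallest other 0.000182), and genes with a gene-end peak in 1 genotype alone numbered 197 (highest other 247). In the region test 0 regions passed for the genotypes, and 0, 12, 15, 16 or 19 for most other splits. The highest count was 57, for the split of Azin2-/- replicate 1 with wild-type replicates 1 and 2b. These are the 3 libraries of lowest background depth, 0.125 to 0.255 fragments per bp against 0.41 to 0.957 in the others, and whether depth gave these calls was not tested.

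Peaks on the X chromosome made up 5.44% of the deposited peaks of Azin2-/- replicate 2 and 4.82% of those of wild-type replicate 2, and between 3.1% and 3.61% in the other libraries.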
